A study of Mus musculus with 4 samples.

How the data were processed

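Gene expression was measured on 4 Affymetrix arrays of mouse bone marrow cells sorted as Lin- c-Kit+ Sca-1+ (KLS), a gate that holds hematopoietic stem and early progenitor cells. According to the labels, 2 arrays held Klf7 knockout cells and 2 held wild-type cells, on a C57Bl/6 background, from chimeric mice built with fetal liver cells of both genotypes. Total RNA was amplified with the NuGen Ovation kit and labelled with biotin, per the labels' protocols. Groups and replicate numbers were taken from the sample titles. The labels do not say how many mice or donor embryos stand behind the arrays. The p-values of single genes therefore measure only the spread between these samples, which may be technical.

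The values deposited by the authors are a single table with an intensity per probe set and array. RMA and Affymetrix Expression Console are named in the submitters' processing notes, without versions or settings. RMA usually gives log2 values, whereas these reached 17720.8, so they were read as intensities on a linear scale and log2 was taken before any test. Median intensity per array lay between 51.01 and 52.26, and the medians and percentiles of the arrays were close enough that no further normalization was applied. Detection calls were not used here, so a fold against a dim group depends on the floor of the arrays. The number of arrays limits the precision of every value.

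The table held 35554 probe sets. The first 6615, which precede the first probe set listed in the annotation, were taken to be control probe sets and left out. No table used here marks controls, so this is an assumption. The other 28939 were tested. The platform annotation, dated 2016, gave 1 symbol for 21789 probe sets and several for 1621, and the remaining 5529 tested probe sets were unlisted. Entrez IDs of 21698 probe sets were found in the RefSeq gene table for GRCm38.p6, which was used for current symbols and for chromosomes only. The symbols covered 19938 genes. The 999 genes with several probe sets were represented by the probe set with the highest mean over the 4 arrays.

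Knockout was compared with wild type in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over all probe sets tested, threshold 0.05), with 2 residual degrees of freedom. All adjusted p-values of genes come from this limma fit, and differences are knockout minus wild type on the log2 scale with the moderated standard error (SE). Genes at least 2-fold apart with no overlap between the groups were counted as a description. Of 38 gene lists, 37 had at least 3 measured members. These were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. At this preset a list is judged mainly against the spread over genes, so its p-value does not measure the spread between arrays. Camera with an estimated correlation and fry were run beside it. Members were also counted after adjustment over the list alone. The lists, the fit, the alternatives and the rule for named genes were fixed before the data were examined.

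The rule named Klf7 first. It then took up to 10 genes per direction past the threshold, by size of change. Where fewer passed, it filled up to 10 with the largest differences among named genes whose mean lay above the median of all genes and whose arrays did not overlap between groups. Of each list described, it took members past the threshold, or else the up to 2 members above the median level with the largest absolute difference. Which 20 lists to describe with named members was decided after the list results were seen. Other genes named are marked as chosen after their values were seen.

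The steps were tested on simulated data that took probe set means and the spread of variances from these arrays. In 10 simulated knockout and wild-type comparisons of 28939 probe sets, 200 probe sets were changed. Limma called 0% of probe sets changed 2-fold, 35% of those changed 4-fold and 90.5% of those changed 16-fold. Calls among many changed probe sets ease the adjusted threshold, so these shares may overstate what can be called where few pass. In the real arrays Scn2a, 26.6-fold apart, had a limma adjusted p of 0.115. Camera at the preset correlation gave p under the threshold in 10 of 10 simulations for the 26 immediate early genes shifted by -0.25. It did so in 0 of 10 for that list unshifted. The list is that of the result reported below, and the shift equals its median. Every simulated member was shifted equally, whereas the quartiles of the measured members were -0.51 and -0.08. Genes were simulated independently, so this does not test camera where members of a list are correlated. Alternatives were a filter on dim probe sets, cyclic loess, repeated quantile normalization, an offset of 32, intensity-dependent variance with and without robust estimation, the replicate number as a block, each array left out, the mean of all probe sets of a gene, and a 1.5-fold threshold. Keeping the leading probe sets, keeping only probe sets with 1 symbol, and leaving out X-linked and Y-linked genes were added after the data were seen.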

Results

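The arrays compared transcript levels in bone marrow KLS cells labelled as knockout or wild type for Klf7, a Kruppel-like zinc finger transcription factor. There were 2 arrays labelled knockout and 2 labelled wild type, called knockout and wild-type arrays by these labels, and 28939 probe sets covering 19938 named genes were tested. Across genes, log2 intensities correlated between arrays with Pearson's r of 0.961 to 0.969, where genes are not independent replicates. Arrays of a group were not consistently closer than arrays of different groups: 702 genes lay at least 2-fold apart between the knockout arrays and 910 between the wild-type arrays, against 724 to 874 between arrays of different genotype.

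Klf7 transcript signal was not lower in the arrays labelled knockout. Its only probe set read 6.59 and 6.18 (log2) in the knockout arrays and 5.95 and 6.10 in the wild-type arrays. The difference was 0.36 ± 0.21 (SE, n = 2 per group; 95% confidence interval -0.18 to 0.91), with an adjusted p of 0.950, and stood at 0.16 without knockout replicate 1. Which part of the gene was deleted is not given in the sources used here, so a probe set outside that part would check nothing and the labels could not be tested with it.

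Xist, the RNA that coats the inactive X chromosome in female cells, was the only gene past the threshold, and it rose by 6.65 ± 0.22 on the log2 scale (SE, n = 2 per group), a 100.4-fold difference with an adjusted p of 0.0454. It read 11.76 and 11.58 in the knockout arrays and 5.24 and 4.80 in the wild-type arrays. Y-linked genes lay the other way. Eif2s3y, a translation initiation factor gene, was at 2.86 and 2.94 in knockout and 6.85 and 8.11 in wild type. Its knockout readings lie at the floor, under the 3.11 that 5% of probe sets fail to reach, so its difference of -4.58 ± 0.44 depends on that floor. Uty, a histone demethylase homologue, differed by -2.88 ± 0.20 and Kdm5d, another histone demethylase gene, by -1.63 ± 0.21. Usp9y and Zfy1 were near the floor in both groups, with wild-type means of 2.78 and 2.87. Over all probe sets, Xist alone of the 6 sex-linked genes passed; adjusted over the list alone, 4 passed, namely Xist, Uty, Eif2s3y and Kdm5d. As a set tested for one direction, the sex-linked list had a camera adjusted p of 0.260. Xist lost its call when any single array was left out, with adjusted p between 0.280 and 0.765, while its difference stayed between 6.43 and 6.87. The sex-linked transcripts divided all 4 arrays exactly as genotype did, so no comparison made here separates genotype from them.

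**Figure D1:**
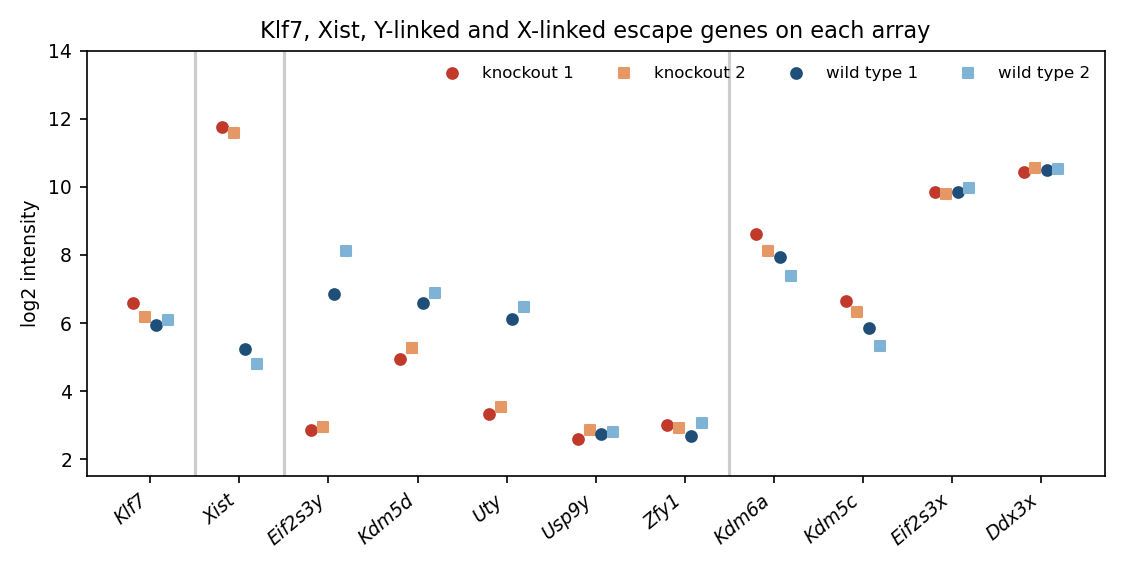
Log2 intensity of Klf7, Xist, the Y-linked genes and 4 X-linked genes known to escape X inactivation, with a point for each of the 4 arrays (knockout in red and orange, wild type in dark and light blue). Xist reads 11.76 and 11.58 in knockout against 5.24 and 4.80 in wild type, while Eif2s3y, Kdm5d and Uty are higher in both wild-type arrays.

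Beyond Xist, no probe set passed in limma, and 1450 had an unadjusted p under 0.05 (727 higher and 723 lower in knockout), where chance gives 1447. The next smallest adjusted p was 0.115, for Scn2a, a neuronal sodium channel gene, which read 9.51 and 9.97 in knockout and 5.09 and 4.92 in wild type. That difference of 4.73 ± 0.22 came from the brightest of 14 Scn2a probe sets, and the differences of the 14 ran from -0.48 to 4.73. The upper end is that probe set itself, and the mean of all 14 differed by only 0.21. Mtmr9, a myotubularin-related gene, was higher by 2.16 ± 0.16 with an adjusted p of 0.326, and its other probe set gave 0.53. Among the other named genes above the median gene level and without overlap between groups, the largest positive differences, none past the threshold, were Spa17 at 2.99 ± 0.98, Uxt at 2.26 ± 0.54, Mrs2 (mitochondrial magnesium channel) at 2.19 ± 0.36, C1galt1c1 (the chaperone of an O-glycosylation enzyme) at 2.02 ± 0.85, Eef1e1 at 2.00 ± 0.87, Gid4 at 1.85 ± 0.85 and the Polycomb gene Phc3 at 1.85 ± 0.88. Single arrays set the size of several of these, so their order is not settled. Without knockout replicate 1, Spa17 stood at 1.54, Uxt at 1.48 and Gid4 at 0.59, and without knockout replicate 2 at 4.44, 3.05 and 3.12. Without wild-type replicate 1, C1galt1c1 stood at 0.80 and Eef1e1 at 1.00, and without wild-type replicate 2, Phc3 stood at 0.58. Both probe sets of Uxt lay above 2, whereas the second probe set of Mrs2 gave 0.03 and that of Phc3 gave -0.26. The genes Uxt and C1galt1c1 are assigned to the X chromosome, and the sex-linked transcripts divided the arrays exactly as genotype did. Where their probe sets map was not checked. The Uxt probe set used (10458428) has an ID between those of Egr1 on chromosome 18 and Klf9 on chromosome 19.

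By the same limits on level and overlap, which leave out the dimmer Eif2s3y and Uty, the 10 largest negative differences were all short of the threshold. An immunoglobulin kappa variable segment (probe set 10545177) differed by -3.37 ± 0.63, the protein kinase C gene Prkch by -2.30 ± 0.45 and Ltb, which encodes lymphotoxin beta, by -1.74 ± 0.29. Ube2h, a ubiquitin-conjugating enzyme gene, read 5.48 and 5.19 in knockout and 7.27 and 7.18 in wild type, a difference of -1.89 ± 0.18 with an adjusted p of 0.648, and its second probe set gave -2.07. Nynrin differed by -2.18 ± 0.71, the tubulin gene Tubb2a by -2.18 ± 0.31, Pmch by -1.64 ± 0.28, the TFIIH subunit gene Gtf2h1 by -1.60 ± 0.21 and the mitochondrial ribosomal protein gene Mrps12 by -1.52 ± 0.24; Kdm5d completes these 10 genes. The second probe set of the kappa segment gave -0.05 and that of Prkch gave -0.64, while the highest of 3 for Nynrin gave 0.21. Nynrin stood at -1.38 without knockout replicate 1. In all, 243 genes lay at least 2-fold apart without overlap, 146 higher and 97 lower in knockout. Leaving out X-linked and Y-linked genes, a setting added after the data were seen, left 225. With all genes kept, grouping the arrays by replicate number gave 243 genes at least 2-fold apart without overlap as well, and the remaining grouping gave 215. Without overlap at any size were 33.2% of genes, where chance gives 33.3%.

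Immediate early genes, which are induced within minutes to hours of a stimulus, fell as a list in the knockout arrays. Of 26 measured, 22 were lower in knockout, 13 of them without overlap between the groups, and the median difference was -0.25 (camera adjusted p = 0.000264). That p-value rests mainly on the spread over genes and not on the spread between the arrays. The call was lost with an estimated correlation (adjusted p = 0.978, on 2 residual degrees of freedom) and with fry's directional test (adjusted p = 0.580). The correlation estimated for the list was 0.044, above the preset of 0.01. Btg2, an antiproliferative gene, differed by -1.08 ± 0.26 and the zinc finger factor gene Egr1 by -0.89 ± 0.23 (SE, n = 2 per group). Among members chosen after their values were seen, Ier2 differed by -0.68 ± 0.22, Junb by -0.56 ± 0.20, and the AP-1 genes Fos and Jun by -0.51 ± 0.16 and -0.51 ± 0.19. No single member passed, either over all probe sets or adjusted over the list alone. Without wild-type replicate 1 the list's median was -0.20 and its adjusted p 0.128, and without knockout replicate 1 the median was -0.14 with an adjusted p of 0.0432.

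**Figure D2:**
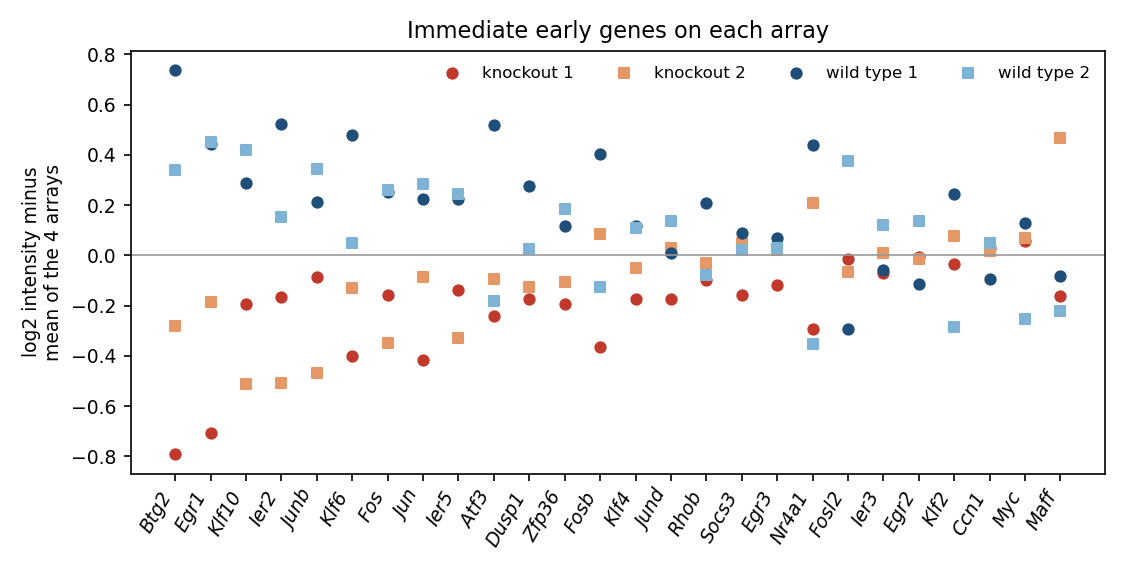
Log2 intensity of each of the 26 immediate early genes on each array, minus the gene's mean over the 4 arrays, ordered by the difference between the groups (knockout in red and orange, wild type in dark and light blue). Knockout points lie below wild-type points for genes at the left, such as Btg2 and Egr1, and mix with them at the right.

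Genes of stem and progenitor identity gave no list past the threshold. The list of 32 HSC genes had a median difference of 0.01 (camera adjusted p = 0.853), with Egr1 at -0.89 ± 0.23 and Mecom, a stem cell transcription factor gene, at -0.71 ± 0.25, although another Mecom probe set gave 0.54. For 19 multipotent and lymphoid progenitor genes the adjusted p was 0.788, with Ighm at 0.92 ± 0.43 and Cd52 at -0.77 ± 0.50, and the probe sets of Ighm ran from -0.56 to 0.92. Of the antigens used in the sort, Kit differed by 0.39 ± 0.17. Ly6e, listed beside them as a relative of the Sca-1 gene and not itself a sort antigen, differed by -0.04 ± 0.41; with 2 measured members this list was not tested. The 39 lineage transcription factors had an adjusted p of 0.853, with Runx3 at -0.63 ± 0.18 and Bcl11a at 0.45 ± 0.24. The 16 other KLF family members (adjusted p = 0.975) divided into 8 higher and 8 lower, with Klf10 at -0.70 ± 0.19 and Klf6 at -0.53 ± 0.23, both also immediate early genes. For 10 genes described as KLF7 targets in neural and metabolic studies the adjusted p was 0.853, and the cyclin-dependent kinase inhibitor genes Cdkn1b and Cdkn1c both differed by 0.07, with SE of 0.20 and 0.33. Single arrays moved several of these values: without wild-type replicate 1, Klf6 stood at -0.31, Mecom at -0.40 and Ighm at 0.49, Bcl11a stood at 0.20 without knockout replicate 1 and Cd52 at -0.12 without knockout replicate 2. No member of these lists passed, adjusted over all probe sets or over the list alone.

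Among proliferation genes, 19 of 27 S phase genes were higher in knockout, with a median of 0.11 and a camera adjusted p of 0.215. Chaf1b, a subunit of the chromatin assembly factor, differed by 0.81 ± 0.15 and the DNA polymerase gene Pole by 0.74 ± 0.23. The 27 G2/M genes (adjusted p = 0.853) held Ndc80 at 1.09 ± 0.37 and Nusap1 at 0.92 ± 0.55, both of which act on the mitotic spindle. The 15 cell cycle inhibitors (adjusted p = 0.975) held Btg2 at -1.08 ± 0.26 and the pocket protein gene Rbl1 at 1.06 ± 0.52. Without wild-type replicate 2, Nusap1 stood at 0.16 and Rbl1 at 0.31, and without knockout replicate 2, Ndc80 stood at 0.59 and Pole at 0.48. No member of the 3 lists passed, adjusted over all probe sets or over the list alone. Without wild-type replicate 1 the S phase list was the only list past the threshold.

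In the stress and inflammation lists, the chaperone gene Hspa1a passed adjusted over the list alone (adjusted p = 0.0307) and not over all probe sets. It read 5.50 and 5.49 in knockout and 6.40 and 6.66 in wild type, a difference of -1.04 ± 0.17. The adjustment over the list alone was made within each of the 37 lists and not across them, so it allows for passes by chance. Hspa5, the chaperone of the endoplasmic reticulum, differed by -0.44 ± 0.15, and the 13 heat shock genes together had a camera adjusted p of 0.788. Of 32 interferon response genes, 17 were higher and 15 lower (adjusted p = 0.853), with Ifitm1 at -1.19 ± 0.23 and the GTPase gene Irgm1 at -1.15 ± 0.41. The 19 NF-kB and inflammatory genes had a median of -0.15 and an adjusted p of 0.691. Within them the chemokine gene Cxcl2 differed by -0.95 ± 0.18 and the cyclooxygenase gene Ptgs2 by 0.87 ± 0.36, and fry's mixed test, which allows either direction, gave an adjusted p of 0.0226. The same mixed test gave 0.0485 for the sex-linked list and 0.0736 for the immediate early list. Irgm1 stood at -0.61 without wild-type replicate 2 and Ptgs2 at 0.43 without knockout replicate 1. No member of the interferon or NF-kB list passed, adjusted over all probe sets or over the list alone.

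The Lin- gate is meant to remove mature blood cells. None of the lists of blood lineage markers passed the threshold, nor did any member, adjusted over all probe sets or over the list alone. These lists do not mark mature cells only, since they hold Flt3 and the pre-B cell gene Vpreb1. The camera adjusted p was 0.807 for 16 T cell genes (Lat at 0.62 ± 0.22, Thy1 at -0.48 ± 0.19) and 0.996 for 15 B cell genes (Cd72 at 1.06 ± 0.26). Vpreb1, part of the pre-B cell receptor, read 8.59 in knockout replicate 1 and between 5.35 and 5.57 on the other arrays, a difference of 1.58 ± 1.03 that was 0.03 without that array. It was 0.852 for 16 erythroid genes, with Car1 at 0.86 ± 0.65 and the band 3 gene Slc4a1 at 0.28 ± 0.16. For 14 megakaryocyte and platelet genes it was 0.853, with Gp5 at -0.52 ± 0.33 and Pf4 at 0.28 ± 0.33. For 19 granulocyte genes it was 0.975, with the granule protein genes Camp at 0.52 ± 0.60 and Ngp at 0.49 ± 0.37. For 22 monocyte, macrophage and dendritic genes it was 0.852, with the lysozyme gene Lyz2 at -0.53 ± 0.37 and Flt3 at 0.48 ± 0.19. Single arrays moved Vpreb1 and 6 other markers by more than 1.5 times. Without knockout replicate 2, Gp5 stood at -0.08 and Lyz2 at -0.03, without knockout replicate 1, Ngp stood at 0.00522 and Camp at -0.37, without wild-type replicate 1, Car1 stood at 0.09, and without wild-type replicate 2, Pf4 stood at -0.13.

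**Figure D3:**
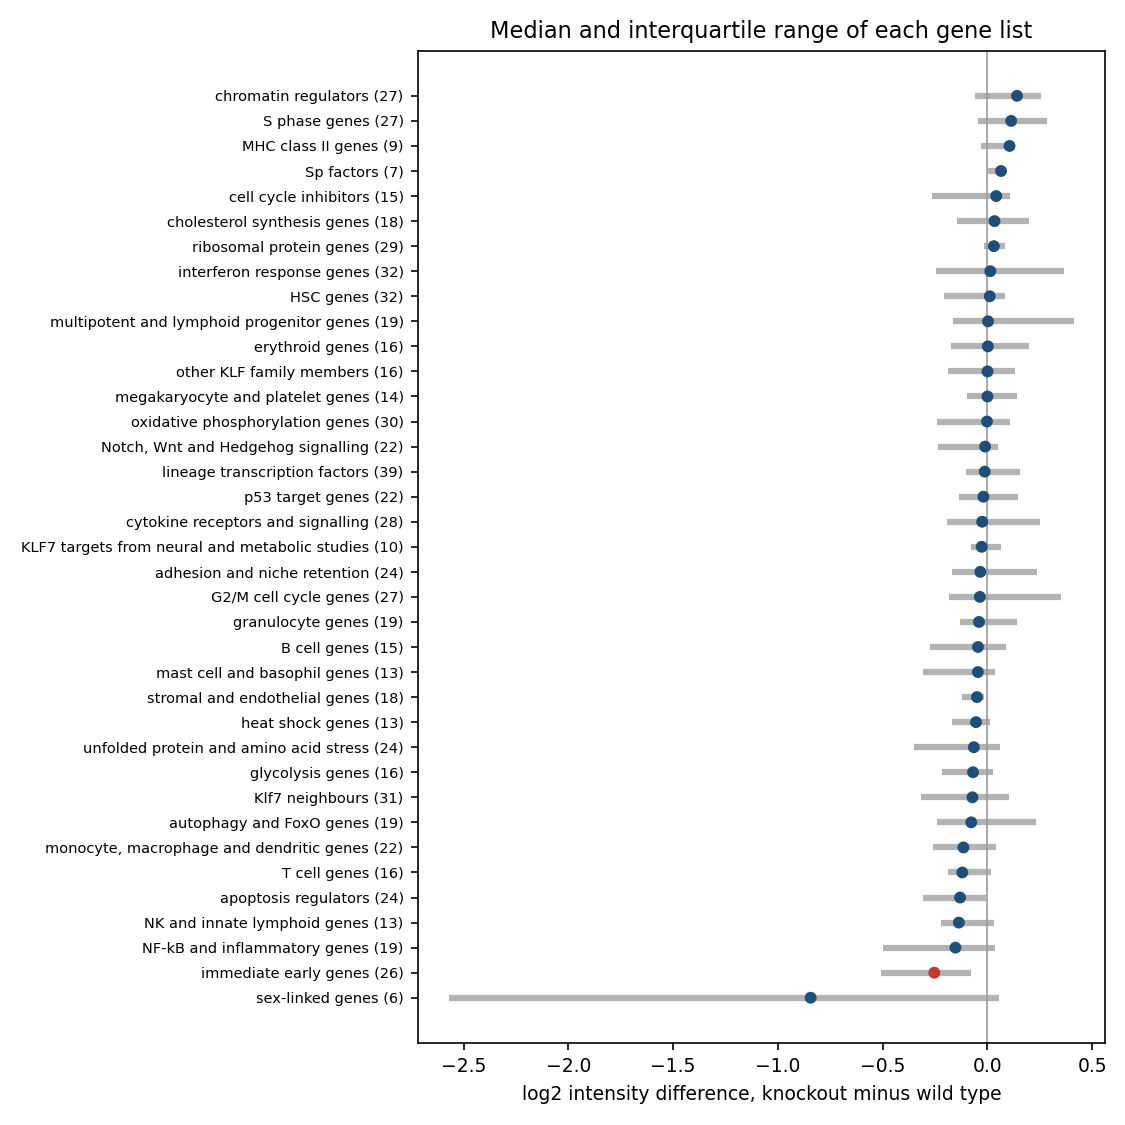
Median log2 difference (knockout minus wild type, points) and interquartile range over members (grey bars) for each of the 37 tested gene lists, with the number of measured members in brackets. The red point marks the immediate early genes, the only list past the camera threshold, with a median of -0.25; the wide bar at the bottom belongs to the 6 sex-linked genes.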

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

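The settings with the leading probe sets kept, with probe sets of 1 symbol only and without X-linked and Y-linked genes were chosen after the data were seen. Xist kept its direction in all 14 alternatives in which it was present, at 5.67 to 6.87 on the log2 scale, and its call in 4 of them, with adjusted p from 0.0160 to 0.765. The limma count of 1 became 0 with quantile normalization again, with an offset of 32, with an intensity trend, with an intensity trend and robust estimation, with the leading probe sets kept (cause not tested) and without X-linked and Y-linked genes (which removes Xist), and was 0 to 0 with each array left out, where a lone array is assumed to vary like the other group. It was also 0 with the replicate block; the labels do not say whether equal numbers mark one mouse, and the deviations of the 2 pairs correlated at 0.0288 across genes. The unadjusted count in the limma fit as reported was 1450. The number of genes 2-fold apart was 99 with an offset of 32, which damps dim probe sets, and 491 to 598 with an array left out, where overlap is easier to avoid; 1024 genes were 1.5-fold apart. The number of lists past the threshold was 0 with an estimated correlation and 0 with fry's directional test. With an estimated correlation, on 2 residual degrees of freedom, every list had an adjusted p of 0.978 to 0.996. Neither setting was tried on simulated shifted lists, so whether either could call such a list is not known. The immediate early genes' median of -0.25 does not depend on the test, and its adjusted p was 0.978 with an estimated correlation and 0.580 with fry; leaving out an array gave medians of -0.35 to -0.14, and the cause of the loss without wild-type replicate 1 was not tested. Klf7 stayed above 0, at 0.16 to 0.57. Small differences turned with an array left out, and the cause was not tested: Camp ran from -0.37 to 1.40, Cdkn1c from -0.36 to 0.50, Ly6e from -0.50 to 0.41, Cdkn1b from -0.12 to 0.26 and Pf4 from -0.13 to 0.70. Over single genes named, 819 values kept direction and side of the threshold, 10 (all Xist) lost the call and 7 reversed. Genes other than Xist were short of the threshold from the start, so keeping their side says little. The 819 also include large changes in size, such as Scn2a from 4.73 to 0.21 with the mean of all its probe sets. Signal over background was not used here, so limits at the dim end rest on the offset and the filter on dim probe sets.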

Other observations

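The tests of mature myeloid cells, of handling and of donor sex as sources of the immediate early pattern were chosen after that result was seen, as was leaving Usp9y and Zfy1 out of the donor sex test. Among lists described only as medians so far, 19 of 27 chromatin regulators were higher in knockout (median 0.14, camera adjusted p = 0.691) and 18 of 24 apoptosis regulators were lower (median -0.13, adjusted p = 0.691). Against the wild-type mean, the chromatin list's median was 0.17 in knockout replicate 1 and 0.00695 in knockout replicate 2, and 6 members were higher and 6 lower without overlap. The 18 lists without named members had medians between -0.14 and 0.14 and adjusted p between 0.691 and 0.975. Cd34, a surface marker that separates multipotent progenitors from the most primitive stem cells in mice, was chosen after its values were seen. It read 10.24 and 10.22 in knockout and 9.65 and 9.57 in wild type, a difference of 0.62 ± 0.15 with a limma adjusted p of 0.945.

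The neutrophil alarmin genes S100a8 and S100a9, also chosen after their values were seen, differed more within groups than between them. S100a8 read 9.59 and 7.54 in knockout and 8.34 and 8.58 in wild type, and S100a9 read 10.40 and 8.02 against 8.80 and 10.09. Some unlisted probe sets lay as far apart as the named genes: probe set 10381695 differed by 4.09 ± 0.26 and probe set 10608138 by -4.39 ± 0.40. Neither has a gene or chromosome in the annotation used, so only the order of IDs bears on whether either is sex-linked. The ID 10608138 follows that of the Y-linked gene Kdm5d (10607972), and this probe set was lower in both knockout arrays, as Kdm5d was. Its difference may therefore be sex-linked. The ID 10381695 lies between those of Sp6 (10380719) and Itgb3 (10381809), both on chromosome 11. Where the 2 unlisted probe sets map was not checked. Of the 243 genes 2-fold apart without overlap, 46 (18.9%) lay below the median gene level. Grouping the arrays by replicate number gave 243 such genes too, so the genotype labels did not separate more genes than another grouping. Pairs of arrays from different groups differed 2-fold in 826.5 genes on average and pairs within a group in 806. Formal tests of these genes against regrouping, spread between arrays and dim signal were drafted, then withdrawn after the regrouped counts had been seen.

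High Xist with low Eif2s3y, Uty and Kdm5d in both knockout arrays is consistent with donors that differ in sex between the groups. The X-linked genes known to escape inactivation had a median difference of 0.35, which rests on Kdm6a at 0.71 ± 0.28 and Kdm5c at 0.89 ± 0.25, since Eif2s3x and Ddx3x differed by -0.10 and -0.01. As first written, this test would have counted against a sex difference if any Y-linked gene was higher in a knockout array. Usp9y and Zfy1 met that wording, but their wild-type means of 2.78 and 2.87 lie below 3.11, the level that 5% of probe sets fail to reach, so they carry no signal to lose, and the test was then limited to the 3 of 5 Y-linked genes above it. A general shift of the X chromosome is argued against by 734 other X-linked genes, whose median was -0.0478 (95% bootstrap interval -0.07 to -0.03). The 264 of them above the median gene level had a median of 0.00419.

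The lower immediate early genes in the knockout arrays may come from chance, genotype, handling, donor sex or cell makeup. More mature myeloid cells in the wild-type arrays, which the Lin- gate is meant to remove, stay open. The 19 granulocyte and monocyte markers had a median of -0.00241, but against the wild-type mean they stood at 0.22 in knockout replicate 1 and -0.17 in replicate 2, where the immediate early list stood at -0.33 and -0.14. Flt3 is among the 19, so they do not mark mature cells only. Handling before lysis that differed between the groups stays open. That both knockout arrays lay below both wild-type arrays restates the pattern and cannot decide this. The heat shock list had a median of -0.0541 with a bootstrap interval over genes of -0.17 to 0.01, which includes 0 and does not decide it either. Donor sex instead of genotype cannot be told apart from genotype, because 0 arrays departed from the Xist pattern of their genotype group. Of the 3 splits of the arrays, only 1, the real one, gave a camera p as small as 7.1e-06, and the others gave 0.849 and 0.0664; 3 splits are too few for a share under 0.05.

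A segment of another strain carried along with the Klf7 mutation could alter its neighbours. The 50 measured genes on each side of Klf7 had a median absolute log2 difference of 0.19, at percentile 93.51 of 10000 random lists matched on mean level, whose median was 0.16. That lies between the bounds set in advance, so the explanation stays open. The 2 neighbours at least 2-fold apart without overlap, chosen after their values were seen, were Acadl at -1.41 ± 0.39 and Bard1 at 1.15 ± 0.42.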
